A study of Mus musculus with 6 samples.

How the data were processed

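RNA sequencing libraries of total RNA from mouse pancreatic islets were compared between Ffar3 knockout (KO) and wild-type (WT) male mice, 3 libraries per group. Groups and replicate numbers came from the sample titles and genotype labels, which describe the replicates as biological and each library as islets pooled from 2 pancreata. Per the submitters' processing notes, the authors used TopHat2 2.0.8b and Cuffdiff 2.1.1 with genome build mm10; gene annotation, strand setting, bias correction and scaling between libraries are not given in the sources used here. The deposited values are taken to be FPKM (fragments scaled by transcript length and by mapped fragments), because Cuffdiff writes that unit and the values are decimals whose sums differ between libraries, from 416935 to 1056340; the files do not name the unit. Median-of-ratios factors computed from the values lay between 0.995 and 1.00, so a scaling of that kind may already be in them. Such values are relative to the other genes of a library, FPKM splits fragments between overlapping genes and near-identical copies by estimate, and trypsin, amylase, small RNA and insulin genes are the most exposed to that.

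Each library had 23179 rows and 22923 distinct symbols; 158 symbols were on more than 1 row and were kept apart, 178 rows joined several symbols, and 5445 rows were at 0 in all libraries. In 22 rows, a library was listed at 0 beside at least 10 FPKM in another (Ins1, Tpd52 and Cacna2d1 among them), which can be a failed estimate; these rows stayed in the tests, and their FPKM are given per library, without a mean. Ins2 was listed at 0 throughout. Total depth is unknown. The FPKM of 1 fragment relative to WT replicate 1 was read from the commonest ratio of values under 0.06 FPKM (window of 0.02 log2 to each side): 0.93, 0.874, 0.841, 1.12 and 1.68 in WT replicates 2 and 3 and KO replicates 1, 2 and 3. With scaled values this measures fragments per FPKM, not the total.

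Values were used as deposited. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma (lmFit, eBayes with a trend, two-sided, group as the only term, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on this scale, which understates the change of genes with low values. Gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry; 29 of 32 lists had at least 3 tested members. Adipocyte and erythroid lists were too small, and mitochondrially encoded genes were not analysed here. List symbols missing from the data were matched through RefSeq synonyms. The named genes were fixed by rule: the fatty acid receptors and islet hormones, the 14 largest rises and 14 largest falls past the threshold with non-overlapping groups (predicted, small RNA and joined symbols left out), and up to 4 members per list of the smallest p, or of the highest mean where none passed. Genes named outside this rule are said to be so, and a few that the rule names are not reported here.

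Positions came from GENCODE M21 on GRCm38, the assembly that mm10 denotes; 98.2% of tested genes had one. The methods were tested on simulated data. From the real means and spreads of 11669 genes, with 200 changed per run in 5 runs, limma recovered 54.8% of genes changed by 0.5 log2, 89.5% at 1 and 97.8% at 2, and 4.44% of its calls were false. For a list shifted by -0.5 log2, camera called it in 5 of 5 runs and called 0 of 140 unshifted lists. The simulated genes varied independently and with the same spread in both groups, which real genes need not do. The real KO libraries were less alike than the WT libraries, KO replicates 2 and 3 had high acinar transcripts, and 4657 genes were called. The simulated rates therefore need not hold for the real comparison. Alternatives fixed in advance were another pseudocount (0.1), no filter or a mean of at least 5 FPKM, rescaling by median-of-ratios factors or to equal sums outside the acinar list, quantile normalization, a robust variance prior, array weights, the replicate number as a block, each library left out, and other set tests. Chosen after seeing the data were KO replicate 1 alone against WT (a single library, taken to vary like the WT libraries), the mean acinar level as a covariate, removal of the 22 rows above, equal sums outside acinar and insulin rows, and the receptor list without Ffar3. The mean log2 acinar level was 7.38 to 7.77 in WT and 7.21, 10.0 and 11.0 in KO replicates 1, 2 and 3. The covariate fit therefore leans on KO replicate 1, and the 2 are not separate checks. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.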

Results

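Gene expression was measured by RNA sequencing in pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from male C57BL/6J mice aged 10 to 14 weeks. The mice either lacked Ffar3 (KO), the gene for a G protein-coupled receptor of short-chain fatty acids, or were wild type (WT). There were 3 libraries per group, described as biological replicates, and each was made from islets pooled from 2 pancreata. Values were FPKM for 23179 gene rows, of which 11669 had a mean of at least 1 FPKM over the 6 libraries and were tested. Total read depth was unknown. Among values under 0.06 FPKM, the commonest ratio to WT replicate 1 was taken as the ratio of 1 fragment, which was not tested. In KO replicate 3 it held for 57 of 368 rows. By this estimate KO replicate 3 had 59.5% and KO replicate 2 had 89.3% of the fragments per FPKM of WT replicate 1. The other libraries lay between 108% and 119%. If so, a low FPKM value in KO replicate 3 rested on the fewest fragments.

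The question was how islet gene expression differs between these KO and WT libraries. Isolation dates, time of day and library batches are not given in the sources used here. Any of these that differed between the groups could not be told apart from genotype. Ffar3 itself was at 4.69, 5.26 and 6.68 FPKM in the WT libraries, listed at 0 in KO replicates 1 and 2, and at 0.105 FPKM in KO replicate 3, so all 6 labels matched the targeted gene. Its log2 difference was -2.65 (SE 0.13, adjusted p = 0.00022). The exact two-sided permutation test of this gene alone gave p = 0.1, the smallest that 3 against 3 allows. Of the 5 other tested receptors of fatty acids and related metabolites, 4 fell, Ffar1 and Ffar2 among them. Of 28 immediate early and stress genes, 22 fell, with Nr4a1 at 493 ± 57.9 FPKM in WT and 72.6 ± 20.1 in KO (mean ± SD, n = 3 per group). The cytoskeletal genes Vcl and Myo1e were among the largest rises, and the beta cell genes Rfx6, Isl1, Ucn3 and Glp1r fell. Transcripts of digestive enzymes, made by the acinar cells around the islets, took 10.6%, 7.07% and 9.56% of the FPKM sum in the WT libraries, 6.78% in KO replicate 1, 40.6% in KO replicate 2 and 57.2% in KO replicate 3. Ins2 was listed at 0 in every library, and Ins1 at 0 in the WT libraries and KO replicate 1. The sums thus lack insulin to an unlike degree, and the shares are approximate.

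Of the 8 fatty acid and metabolite receptors in the data, 6 were tested and 5 fell, over all genes and adjusted over the list alone. These counts include Ffar3, the targeted gene, and without it 4 of 5 fell in both. Ffar1, the receptor of long-chain fatty acids on beta cells, fell from 34.1 ± 2.55 to 14.8 ± 0.764 FPKM (mean ± SD, n = 3 per group; log2 difference -1.15, SE 0.07, adjusted p = 0.00032). Ffar2, which like Ffar3 binds short-chain fatty acids, fell from 9.63 ± 0.665 to 4.84 ± 0.311 FPKM (log2 difference -0.86, adjusted p = 0.00064). Gpr119, a receptor of lipid amides, fell from 6.16 ± 0.341 to 2.87 ± 0.322 FPKM. The niacin receptor Hcar2, listed under its older symbol Niacr1 and named after its values were seen, fell from 11.1 ± 1.1 to 6.66 ± 0.934 FPKM. Ffar4, listed as O3far1, was at 7.69 ± 1.12 FPKM in WT and 8.04 ± 2.38 in KO (log2 difference 0.03, adjusted p = 0.89). With the acinar level as a covariate it was called higher (0.38, adjusted p = 0.047), and in KO replicate 1 alone it was at 0.44. The covariate fit leans on KO replicate 1, the only KO library with an acinar level near WT, so these are not separate checks. The median log2 difference of the list was -0.88, with a camera adjusted p of 0.0011 and adjusted p = 0.58 with an estimated correlation. Without Ffar3 the median was -0.86, with a camera adjusted p of 0.0082 and adjusted p = 0.84 with an estimated correlation. Ffar1 and Ffar2, which lie 1.2 kb and 30.6 kb from Ffar3, were still in that list. Its result is therefore not free of the targeted locus, and the list was not tested without them.

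**Figure D1:**
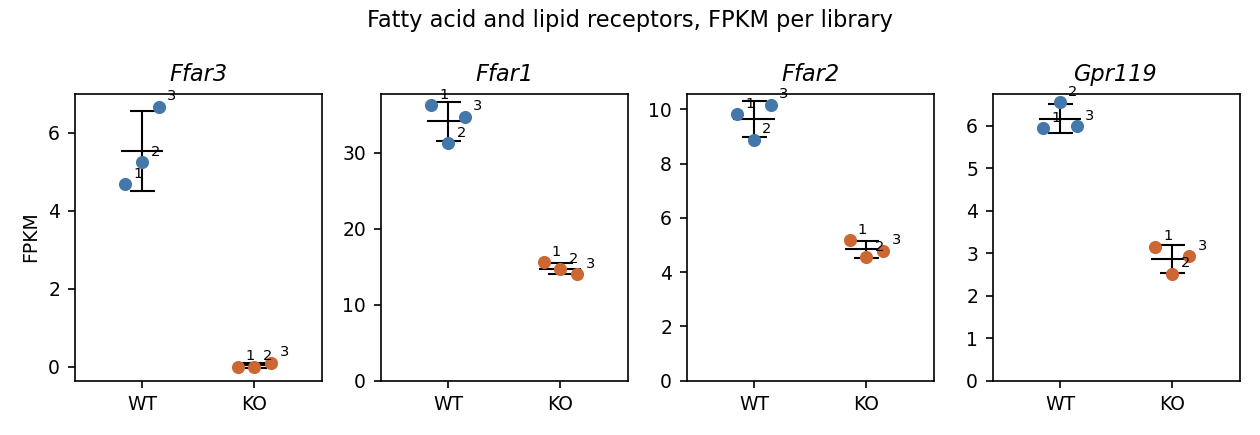
FPKM per library (y axis) of Ffar3, Ffar1, Ffar2 and Gpr119 in WT and KO islets; points are libraries numbered by replicate, and bars are the mean and SD of 3. For each gene the 3 KO libraries lie below the 3 WT libraries, for Ffar1 between 14.0 and 15.5 FPKM against 31.3 to 36.3.

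Across the 11669 genes, 4657 (39.9%) differed between KO and WT in limma at an adjusted p under 0.05, 2368 higher and 2289 lower in KO. Of these, 324 were at least 1 log2 unit apart, 237 higher and 87 lower. The counts of called members given for each gene list are to be read beside the share of 39.9% over all tested genes. The 3 KO libraries lay on one side of the 3 WT libraries for 56.3% of tested genes, against 10% by chance. KO replicate 1, the KO library without high acinar transcripts, was also set alone against WT. That comparison assumes that this single library varies like the WT libraries, and as a part of the whole comparison it is not independent of it. It called 3013 genes, of which 2640 were among the 4657 and 267 among the 324 large differences. The count fell to 2482 without WT replicate 1 and to 2518 without WT replicate 3, and the count of large differences rose to 585 without KO replicate 1.

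The largest rises included genes of the cytoskeleton and of metabolism that were alike in the 3 KO libraries. Log2 differences are on the scale of log2(FPKM + 1), which compresses changes of low values. Myo1e, a class I myosin, rose from 2.11 ± 0.143 to 24 ± 0.897 FPKM (log2 difference 3.01, SE 0.06, adjusted p = 5.0e-06). Vcl, which encodes the adhesion protein vinculin, rose from 7.17 ± 1.26 to 46.8 ± 3.09 FPKM, and the kinase gene Sgk2 from 3.13 ± 0.317 to 22.4 ± 1.85 FPKM. Cyp1a1, a cytochrome P450 of xenobiotic metabolism, rose from 0.142 ± 0.0584 to 5.06 ± 1.27 FPKM. Other large rises differed widely between KO libraries. The duct keratin Krt19 was at 3.35, 23.3 and 30.8 FPKM in KO replicates 1, 2 and 3 against a WT mean of 0.964 ± 0.146, Lfng at 2.07, 13.6 and 21 against 0.452 ± 0.284, Sprr1a at 2.88, 18.8 and 12 against 0.232 ± 0.118, and Ly6d at 3.71, 9.49 and 3.19 against 0.0518 ± 0.0451. The trypsin gene Prss3 was at 19.2, 271 and 557 FPKM against 13.3 ± 2.23, highest in KO replicates 2 and 3, where the acinar share was high. In KO replicate 1, where that share was below each WT library, Prss3 still lay above the highest WT value of 15.3. With the acinar level as a covariate its log2 difference was 1.05 (adjusted p = 0.0011). Igj, the joining chain of antibodies, was at 47.3, 75.9 and 6.74 FPKM, Plac8 at 7.74, 16.1 and 3.07, Ccr7 at 7.02, 29.4 and 1.53, and the B cell coactivator Pou2af1 at 8.10, 11.2 and 0.743, against WT values of at most 0.413 for Igj, 0.655 for Plac8, 0.376 for Ccr7 and 0.0197 for Pou2af1. The calls of Krt19, Lfng, Pou2af1, Ccr7 and Prss3 were lost in some fits that left out 1 library, while their log2 differences in those fits stayed between 1.98 and 3.45. With a robust variance prior their adjusted p was 0.059, 0.06, 0.072, 0.099 and 0.13. Without WT replicate 2 their adjusted p was 0.051, 0.053, 0.067, 0.089 and 0.12, and without WT replicate 3 it was 0.053, 0.061, 0.071, 0.088 and 0.11. Without WT replicate 1 it was 0.052, 0.073, 0.09 and 0.11 for Krt19, Pou2af1, Ccr7 and Prss3. Without KO replicate 2 it was 0.0502, 0.055, 0.063 and 0.13 for Krt19, Lfng, Pou2af1 and Prss3, and without KO replicate 3 0.097 for Prss3. With no filter on low values it was 0.062 for Ccr7 and 0.085 for Prss3. With the replicate block it was 0.055 for Prss3, and with the acinar level as a covariate 0.067 for Ccr7.

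Immediate early genes, which cells switch on within minutes of a stimulus or stress, were among the largest falls. Of 28 tested members of the list, which also holds heat shock genes, 22 fell and 2 rose over all genes, and 23 fell and 2 rose adjusted over the list alone. The orphan nuclear receptor Nr4a1 fell from 493 ± 57.9 to 72.6 ± 20.1 FPKM (log2 difference -2.77, SE 0.20, adjusted p = 0.00037). The AP-1 genes Fosb and Fos fell from 931 ± 114 to 154 ± 42.5 FPKM and from 357 ± 57.2 to 102 ± 30.8. Atf3 fell from 223 ± 8.29 to 48.8 ± 15.5, Arc from 89.2 ± 12.6 to 20.3 ± 3.41, Nr4a2 from 20.3 ± 2.69 to 5.10 ± 0.607 and Egr4 from 11.5 ± 0.687 to 1.18 ± 0.305. The inducible chaperone Hspa1b fell from 503 ± 22.6 to 139 ± 42.0 FPKM. Myc and Hspb1, named as the 2 exceptions after their values were seen, rose by log2 differences of 1.91 and 0.37. Hspb1 did not pass without WT replicate 1, WT replicate 3 or KO replicate 2 (adjusted p of 0.1, 0.081 and 0.0514). The list varied 2.63 times as much within groups as lists matched on mean expression. The median of the list was -1.22 (camera adjusted p = 1.1e-08; adjusted p = 0.58 with an estimated correlation), and in KO replicate 1 alone the median was -1.23 with 23 members lower. Outside the list, the falls included the chaperones Dnajb1 (793 ± 45.8 to 166 ± 38.0 FPKM) and Dnajb4 (120 ± 12 to 32.6 ± 2.92), the clock gene Per1 (71.9 ± 11.2 to 15.1 ± 2.18), C2cd4a (38.7 ± 5.49 to 8.61 ± 4.01), Rasd1 (56.2 ± 10.8 to 14.1 ± 5.75) and the orphan receptor Gpr6 (5.96 ± 0.438 to 0.998 ± 0.633).

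**Figure D2:**
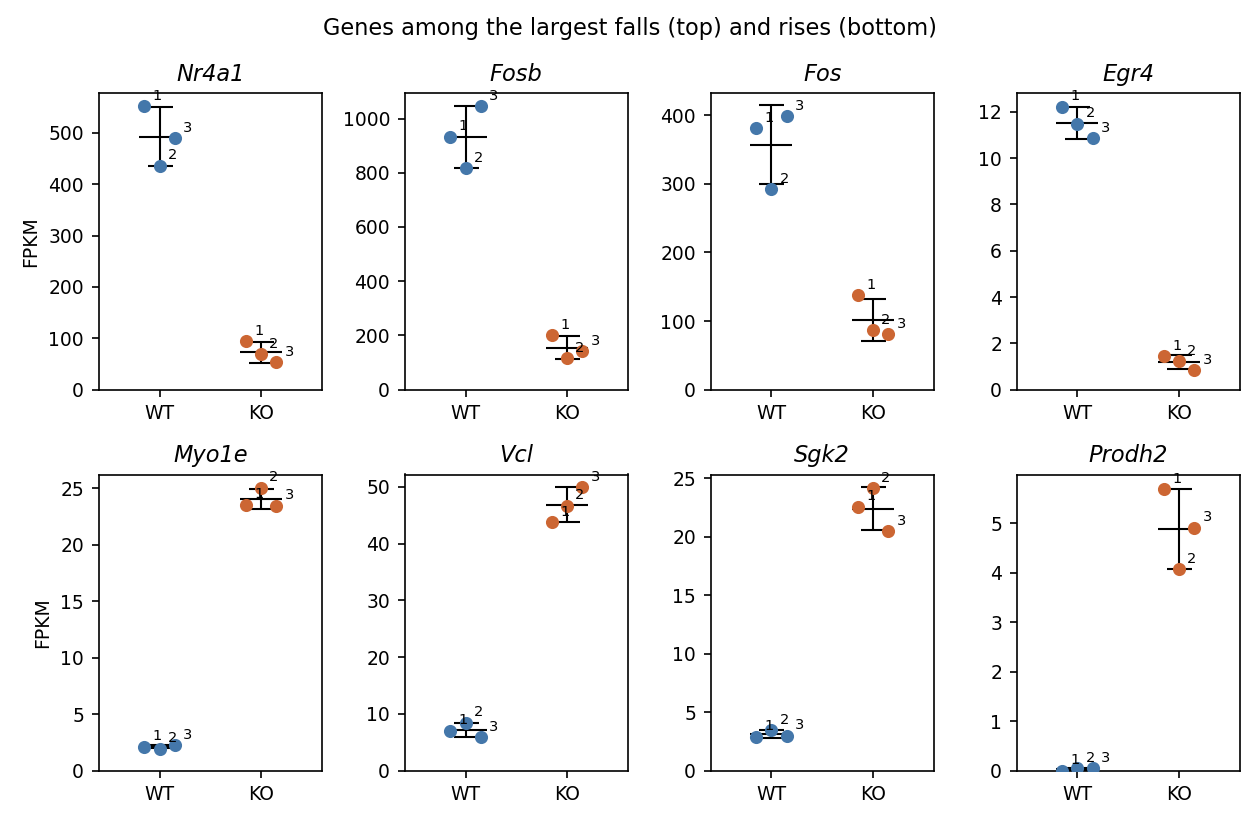
FPKM per library (y axis) of 4 genes among the largest falls (Nr4a1, Fosb, Fos, Egr4) and 4 among the largest rises (Myo1e, Vcl, Sgk2, Prodh2); points are libraries numbered by replicate, bars the mean and SD of 3. The groups do not overlap for any of the 8 genes, and Nr4a1 lies between 54.0 and 94.0 FPKM in KO against a WT mean of 493.

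Beta cell genes fell more often than they rose: of 29 tested, 14 fell and 1 rose, over all genes and adjusted over the list alone. Rfx6, a transcription factor of endocrine cells, fell from 26.9 ± 0.789 to 12.8 ± 1.47 FPKM (log2 difference -1.02, adjusted p = 0.00052), Isl1 from 50.9 ± 4.48 to 25.9 ± 4.53, the peptide gene Ucn3 from 340 ± 21.5 to 188 ± 29.2 and the incretin receptor Glp1r from 102 ± 4.68 to 67.0 ± 4.15. The median of the list was -0.24, while its mean was 0.03 with Ins1 in it. Camera gave an adjusted p of 0.0088 toward lower, and the list had adjusted p = 0.84 with an estimated correlation. In KO replicate 1 alone, where the acinar share was below that of each WT library, the median was -0.12 (adjusted p = 0.067). With the acinar level as a covariate it was -0.14 (adjusted p = 0.031). The insulin genes could not be compared. Ins2 was listed at 0 in all 6 libraries. Ins1 was listed at 0 in the WT libraries and KO replicate 1, and at 43721 and 48334 FPKM in KO replicates 2 and 3.

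Genes of calcium channels and exocytosis also leaned lower, with 13 of 36 lower and 0 higher (9 lower adjusted over the list alone). Rph3al fell from 52.2 ± 2.01 to 38.1 ± 3.62 FPKM, the syntaxin gene Stx4a from 16.9 ± 0.517 to 11.9 ± 1.40, the inositol trisphosphate receptor gene Itpr3 from 10.4 ± 0.218 to 8.29 ± 0.0934 and the calcium channel gene Cacna1a from 8.96 ± 0.191 to 6.87 ± 0.441. Camera gave an adjusted p of 0.0088, adjusted p = 0.84 with an estimated correlation, and 0.18 in KO replicate 1 alone, where Cacna1a did not pass either (adjusted p = 0.053). Acinar transcripts were high in the other KO libraries, and with the acinar level as a covariate the median went from -0.22 to -0.1 (adjusted p = 0.066). Of 39 genes of G protein and cAMP signalling, 13 fell and 6 rose (15 and 8 adjusted over the list alone), and the list as a set did not pass (adjusted p = 0.18). The phosphodiesterase gene Pde10a fell from 4.49 ± 0.338 to 1.65 ± 0.303 FPKM and Gng12 from 219 ± 16.4 to 126 ± 13.6. The inhibitory G protein genes Gnaz (18.1 ± 1.15 to 27.9 ± 0.574) and Gnai3 (59.5 ± 2.64 to 85.2 ± 5.10) rose. Other genes of that class, Gnai2 (180 ± 0.458 to 139 ± 12.3) and Gnao1 (89.9 ± 0.213 to 66.8 ± 6.66), named after their values were seen, fell.

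Among the other endocrine cells, 4 of 11 alpha cell genes and 1 of 5 delta cell genes fell and 0 rose; adjusted over the list alone these were 4 and 5. The alpha cell gene Slc7a2 fell from 44.7 ± 1.29 to 31.2 ± 3.08 FPKM. The delta cell factor Hhex fell from 7.30 ± 0.751 to 3.55 ± 1.28 and had an adjusted p of 0.0506 without WT replicate 1. Irx1, Irx2 and Tmem27 also fell by log2 differences of -0.51, -0.38 and -0.43, and each lost its call when single libraries were left out. Without WT replicate 2 the adjusted p was 0.11, 0.13 and 0.11, without WT replicate 3 0.075, 0.12 and 0.11, and without KO replicate 3 0.077, 0.091 and 0.1. Irx1 and Tmem27 also lost it without WT replicate 1 (0.066 and 0.14) and KO replicate 2 (0.091 and 0.12), and Irx2 without KO replicate 1 (0.054). With no filter on low values the adjusted p of Irx1, Irx2 and Tmem27 was 0.062, 0.073 and 0.074. With the acinar level as a covariate it was 0.16, 0.15 and 0.12. In KO replicate 1 alone their log2 differences were -0.24, -0.36 and -0.12. Equal sums outside the acinar list ended the calls of Irx2 (0.052) and Tmem27 (0.068), and quantile normalization that of Tmem27 (0.067). Glucagon (Gcg) was at 12436, 8534 and 6474 FPKM in the KO libraries against a WT mean of 20303 ± 2211 (adjusted p = 0.07, 0.032 in KO replicate 1 alone and 0.0046 without it). Gcg was called lower with the acinar level as a covariate (log2 difference -0.76, adjusted p = 0.0088), with equal sums outside the acinar list (0.026), with a robust prior (0.0063) and with array weights (0.025). Somatostatin (Sst) was at 3243 ± 1125 against 5155 ± 142 (adjusted p = 0.083, 0.002 without KO replicate 1, 0.032 with a robust prior and 0.024 with array weights). The log2 difference of Sst was -0.72, but -0.18 in KO replicate 1 alone and -0.30 with the acinar level as a covariate (adjusted p = 0.064). Pancreatic polypeptide (Ppy) was at 6507 ± 1056 against 7405 ± 1106 FPKM and Pyy at 1525 ± 338 against 2102 ± 84.3 (adjusted p = 0.081, 0.0033 without KO replicate 1, 0.037 with a robust prior and 0.027 with array weights), and 0 of 3 PP cell genes passed (set adjusted p = 0.95). For Pyy the log2 difference was -0.48, but -0.13 in KO replicate 1 alone and -0.21 with the acinar level as a covariate (adjusted p = 0.12). The alpha and delta sets had adjusted p of 0.046 each, adjusted p = 0.84 with an estimated correlation, and 0.23 each in KO replicate 1 alone. They also missed it without WT replicate 2 (0.081 each), KO replicate 2 (0.087 and 0.086) or KO replicate 3 (0.083 each), and the delta set without WT replicate 3 (0.0515). Acinar transcripts were high in KO replicates 2 and 3, and with the acinar level as a covariate the alpha and delta medians went from -0.43 and -0.57 to -0.19 and -0.21 (adjusted p of 0.097 and 0.085). Both sets also missed with equal sums outside the acinar list (0.061 and 0.067), under quantile normalization (0.095 and 0.081) and at a mean of at least 5 FPKM (0.12 and 0.066), and the alpha set without a filter (0.0504).

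Several metabolic groups had members that changed. Across all tested genes 39.9% were called, so a count near or below that share does not set a list apart. Of 12 tested genes that beta cells normally keep low, 5 rose and 0 fell (8 higher adjusted over the list alone), among them lactate dehydrogenase Ldha (9.60 ± 0.647 to 20.4 ± 5.74 FPKM), Tgm2 (1.40 ± 0.0263 to 4.17 ± 2.07), Cd44 (8.19 ± 0.176 to 13.1 ± 3.21) and Mgst1 (0.834 ± 0.181 to 2.96 ± 1.33). Other pancreatic cells express these genes, and Tgm2, Cd44 and Mgst1 did not pass without WT replicate 1 (adjusted p of 0.061, 0.059 and 0.053), WT replicate 2 (0.057, 0.0585 and 0.066) or WT replicate 3 (0.059, 0.061 and 0.065), nor Mgst1 without KO replicate 2 (0.06). The set passed with an adjusted p of 0.034, adjusted p = 0.84 with an estimated correlation, and 0.2 in KO replicate 1 alone, and missed without WT replicate 3 (0.053), KO replicate 2 (0.057) or KO replicate 3 (0.075). With the acinar level as a covariate its adjusted p was 0.15, at a mean of at least 5 FPKM 0.17, and with equal sums outside acinar and insulin rows 0.061. In lipid and cholesterol synthesis 8 of 23 genes rose and 1 fell, the same adjusted over the list alone: the elongase gene Elovl6 rose from 6.17 ± 0.318 to 9.96 ± 0.261 FPKM, squalene synthase Fdft1 from 30.9 ± 3.64 to 49.0 ± 1.83, Me1 from 7.47 ± 0.745 to 12.4 ± 1.22 and the regulator Srebf2 from 39.2 ± 4.03 to 58.4 ± 2.69. That set had an adjusted p of 0.027, adjusted p = 0.84 with an estimated correlation, and 0.13 in KO replicate 1 alone, 0.072 without WT replicate 1 and 0.083 without KO replicate 3. With the acinar level as a covariate it was 0.097.

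Fatty acid oxidation and short-chain fatty acid use had 4 of 27 genes higher and 1 lower, adjusted over the list alone as well, and did not pass as a set (adjusted p = 0.44). Cpt1a, which carries fatty acids into mitochondria, rose from 10.3 ± 0.434 to 21.7 ± 3.04 FPKM, Acsl4 from 9.21 ± 0.805 to 14.3 ± 0.547 and the lactate transporter gene Slc16a3 from 1.10 ± 0.0972 to 2.35 ± 0.585. Slc16a3 had an adjusted p of 0.054 without WT replicate 3. Acadl rose by a log2 difference of 0.22 and lost its call without WT replicate 1, WT replicate 3 or KO replicate 2 (adjusted p of 0.082, 0.095 and 0.059). With equal sums outside the acinar list Acadl was at 0.16 (adjusted p = 0.19). It also missed under quantile normalization (0.053) and with the acinar level as a covariate (0.056). Glycolysis had 3 higher and 5 lower of 19, the same over the list alone (set adjusted p = 0.93): Pfkp (7.07 ± 0.127 to 12.8 ± 1.42 FPKM) and Pgk1 (77.2 ± 2.87 to 101 ± 9.30) rose, Pfkm (23.4 ± 0.957 to 17.8 ± 1.64) and Pklr (5.45 ± 0.299 to 3.90 ± 0.247) fell. Of 77 nuclear genes of the respiratory chain, 8 fell and 0 rose (0 adjusted over the list alone), with Ndufb3 from 73.2 ± 2.30 to 59.3 ± 2.39 FPKM, Ndufs7 from 69.1 ± 1.10 to 57.3 ± 2.50, Sdhc from 84.1 ± 2.88 to 67.2 ± 5.36 and Ndufs3 from 79.4 ± 2.23 to 64.8 ± 5.07. The last 3 did not pass without WT replicate 1 (adjusted p of 0.053, 0.054 and 0.071), nor Sdhc and Ndufs3 without WT replicate 3 (0.06 and 0.072). The median was -0.1, with a camera adjusted p of 0.0088, adjusted p = 0.84 with an estimated correlation, 0.0024 in KO replicate 1 alone and 0.086 without KO replicate 2. Under quantile normalization it was 0.095.

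Stress and growth genes moved both ways. In the unfolded protein response 11 of 30 genes rose and 4 fell (12 and 4 adjusted over the list alone; set adjusted p = 0.17). The sensors Atf6 (26.7 ± 0.991 to 38.5 ± 1.23 FPKM) and Ern1 (27.0 ± 1.19 to 44.8 ± 4.28) rose, as did Sel1l (39.7 ± 3.50 to 127 ± 35.0), which was highest in the acinar-rich KO replicate 3 at 166 FPKM. Ppp1r15a fell from 233 ± 21.3 to 115 ± 15.9. Of 15 hypoxia genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone). P4ha2 (9.43 ± 0.324 to 13 ± 0.850 FPKM), Kdm3a (7.02 ± 0.350 to 10.7 ± 1.11) and Hilpda (11.2 ± 1.82 to 17.9 ± 2.09) rose and Ankrd37 (10.1 ± 0.429 to 6.10 ± 1.33) fell. Camera gave an adjusted p of 0.13 and fry 0.0040. Of 17 cell cycle genes, 4 rose and 2 fell, also over the list alone (set adjusted p = 0.56). The inhibitor gene Cdkn1a rose from 48.9 ± 3.43 to 106 ± 8.25 FPKM, Rrm2 from 1.73 ± 0.0171 to 3.17 ± 0.346 and Mcm6 from 4.32 ± 0.283 to 6.95 ± 1.21, and cyclin D1 (Ccnd1) fell from 59.2 ± 3.22 to 35.4 ± 1.58. Cytosolic ribosomal proteins had 3 of 80 higher and 0 lower (1 adjusted over the list alone), Rpl7l1 rising from 19.3 ± 0.501 to 24.3 ± 0.559 FPKM. Rps15a and Rps19 rose by log2 differences of 0.33 and 0.38 and kept their calls without KO replicate 1 only. Without WT replicates 1, 2 and 3 and KO replicates 2 and 3 the adjusted p was 0.11, 0.093, 0.1, 0.1 and 0.087 for Rps15a, and 0.11, 0.1, 0.13, 0.098 and 0.076 for Rps19. Their median of 0.20 (adjusted p = 0.00027; adjusted p = 0.84 with an estimated correlation) was 0.02 in KO replicate 1 alone (adjusted p = 0.46) and 0.03 with the acinar level as a covariate (adjusted p = 0.2).

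Interferon response and antigen presentation had 9 of 27 genes higher and 1 lower, the same adjusted over the list alone. Gbp2 rose from 1.49 ± 0.154 to 5.13 ± 1.33 FPKM, the RNA sensor gene Ddx58 from 6.43 ± 0.912 to 11.8 ± 0.944 and H2-D1 from 224 ± 14.0 to 306 ± 14.7, while Irf1 fell from 116 ± 14.1 to 52.1 ± 3.58. The set passed with an adjusted p of 0.011, and had adjusted p = 0.84 with an estimated correlation. Among genes with a mean of at least 5 FPKM it was 0.062. The median of the list was 0.43, and 0.32 in KO replicate 1 alone. Its members summed to 1050, 1278 and 891 FPKM in KO replicates 1, 2 and 3 against 840 to 889 in WT, so KO replicate 3 was near the WT level. Cytokines and acute inflammation had 5 higher and 6 lower of 21, also over the list alone (set adjusted p = 0.93): the NF-kappaB subunit genes Nfkb2 (11.1 ± 1.19 to 30.5 ± 3.59 FPKM) and Nfkb1 (13.9 ± 0.211 to 31.2 ± 4.95) rose, and Tnf (11.5 ± 3.00 to 3.47 ± 0.974) and Ccl3 (25.4 ± 3.75 to 9.53 ± 2.43) fell. Lymphocyte genes summed to 44.1, 108 and 11.4 FPKM in KO replicates 1, 2 and 3 against 7.47 to 8.31 in WT. Of 8 tested, 2 rose and 0 fell (8 higher adjusted over the list alone), Ccr7 and Ms4a1. Genes were tested by their mean over all libraries, so members near 0 in WT could pass that filter only through high KO values. The direction of these counts and of the set was therefore partly fixed by the filter. The B cell antigen gene Ms4a1 was listed at 0 in the WT libraries and at 3.37, 6.32 and 0.311 FPKM in KO. Ms4a1 had an adjusted p of 0.11, 0.1, 0.11 and 0.077 without WT replicates 1, 2 and 3 and KO replicate 1, and Ccr7 0.09, 0.089 and 0.088 without WT replicates 1, 2 and 3. With no filter on low values Ms4a1 was at 0.073 and Ccr7 at 0.062, and with a robust variance prior at 0.094 and 0.099. The lymphocyte set had an adjusted p of 0.024, adjusted p = 0.84 with an estimated correlation, 0.087 without KO replicate 1 and 0.12 without KO replicate 2. Macrophage and dendritic cell genes had 1 of 16 lower and 0 higher (0 adjusted over the list alone; set adjusted p = 0.46): C1qa fell from 55.9 ± 3.83 to 43.2 ± 6.49 FPKM and passed without KO replicate 1 only (adjusted p of 0.11, 0.054, 0.12, 0.086 and 0.067 without WT replicates 1, 2 and 3 and KO replicates 2 and 3). The macrophage set passed toward higher without KO replicate 3 (adjusted p = 0.012) and in KO replicate 1 alone (0.048).

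**Figure D3:**
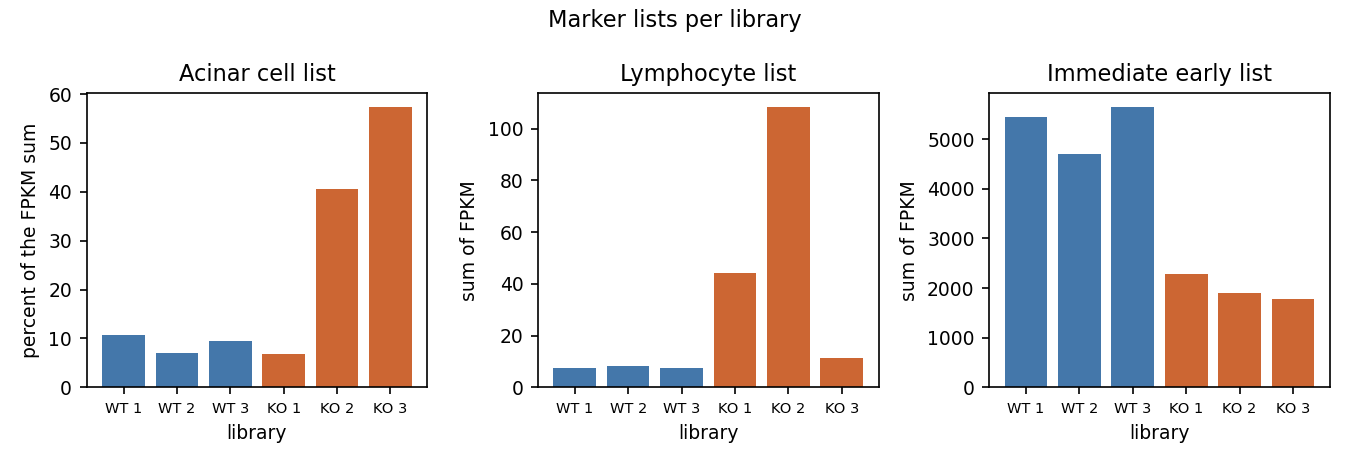
Bars give, for each of the 6 libraries (x axis), the acinar cell list as a percent of the FPKM sum and the FPKM sums of the lymphocyte and immediate early lists (y axes). The percents are approximate, because insulin rows listed at 0 leave gaps in the sums. Acinar transcripts reach 40.6% and 57.2% in KO replicates 2 and 3 only, lymphocyte genes are highest in KO replicate 2 (108 FPKM), and immediate early genes are lower in all 3 KO libraries, at 1781 to 2276 against 4697 to 5637.

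The acinar cell list had the highest median difference of any list, 2.1, but 1 of 36 members passed the threshold (Prss3, and 0 adjusted over the list alone) and the KO libraries differed from each other. In KO replicates 2 and 3 the list lay above the highest WT library at all 34 markers without a listed 0. Its camera adjusted p was 0.0032, adjusted p = 0.84 with an estimated correlation, and in KO replicate 1 alone the direction was lower (median -0.46, adjusted p = 0.0024). Of 12 duct cell genes, 3 rose and 0 fell, adjusted over the list alone as well: Epcam rose evenly from 71.8 ± 5.31 to 135 ± 6.04 FPKM, Anxa2 was at 13.6, 37.6 and 26.2 in the KO libraries against 7.53 ± 0.599, and Krt19 rose as well (adjusted p = 0.015). The duct set had an adjusted p of 0.010, adjusted p = 0.84 with an estimated correlation, and 0.083 in KO replicate 1 alone. Its median went from 1.02 to 0.36 with the acinar level as a covariate (adjusted p = 0.031). Of 13 endothelial genes, 1 rose and 4 fell (same over the list alone; set adjusted p = 0.17, and 0.043 toward lower without WT replicate 2). Cdh5 rose from 6.13 ± 0.683 to 10.4 ± 2.02 FPKM and Esm1 fell from 49.4 ± 3.91 to 38.6 ± 1.16. Kdr and Emcn fell by log2 differences of -0.56 and -0.36 and did not pass without WT replicate 1 (adjusted p of 0.075 and 0.087) or WT replicate 3 (0.072 and 0.077), nor Emcn without KO replicate 2 (0.0506). Stellate and mesenchymal genes had 2 of 11 lower, Acta2 and Pdgfrb (0 adjusted over the list alone; set adjusted p = 0.11), and neither passed without WT replicate 1 (adjusted p of 0.096 and 0.11) or WT replicate 3 (0.091 and 0.17). Pdgfrb missed without WT replicate 2 (0.065) and KO replicates 1, 2 and 3 (0.059, 0.066 and 0.089) as well. Without KO replicate 2 that set had an adjusted p of 0.037.

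Collagens had 4 of 9 lower and 0 higher (6 lower adjusted over the list alone), such as Col6a6, from 8.42 ± 0.311 to 6.09 ± 0.372 FPKM, and Col13a1, from 4.09 ± 0.710 to 2.27 ± 0.233. Col27a1 and Col9a2 fell by log2 differences of -0.48 and -0.37 and did not pass without WT replicate 1 (adjusted p of 0.088 and 0.11) or WT replicate 3 (0.089 and 0.088), nor Col27a1 without WT replicate 2 (0.056) and Col9a2 without KO replicate 3 (0.056). The set had an adjusted p of 0.046 and adjusted p = 0.84 with an estimated correlation. Without WT replicates 1, 2 and 3 it was 0.085, 0.07 and 0.17, and without KO replicates 1 and 3 it was 0.19 and 0.093. In KO replicate 1 alone it was 0.064, with the acinar level as a covariate 0.085 and with the replicate block 0.059. Without a filter the median of the collagens was -0.02 (0.078), and at a mean of at least 5 FPKM it was 0.08 (0.77). Of 6 Schwann cell and neuron genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone; set adjusted p = 0.13): tyrosine hydroxylase (Th) fell from 26.8 ± 2.62 to 17.7 ± 2.06 FPKM and Mbp rose from 28.7 ± 1.90 to 40.6 ± 2.89. Gap43 fell by a log2 difference of -0.73, with an adjusted p of 0.072 without WT replicate 1 and 0.063 without WT replicate 2. The Y-linked genes Ddx3y (24.7 ± 2.31 and 24.6 ± 1.54 FPKM) and Eif2s3y (21.8 ± 0.286 and 20.1 ± 1.36) were expressed in both groups, and 0 of 4 sex-linked genes passed (set adjusted p = 0.95). Of lists too small to test as sets, the adipocyte genes Fabp4 (6.21 ± 0.879 to 11 ± 1.92 FPKM) and Pparg (5.76 ± 0.112 to 8.15 ± 0.930) rose and the globin gene Beta-s fell from 17.4 ± 4.09 to 10.4 ± 1.33.

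**Figure D4:**
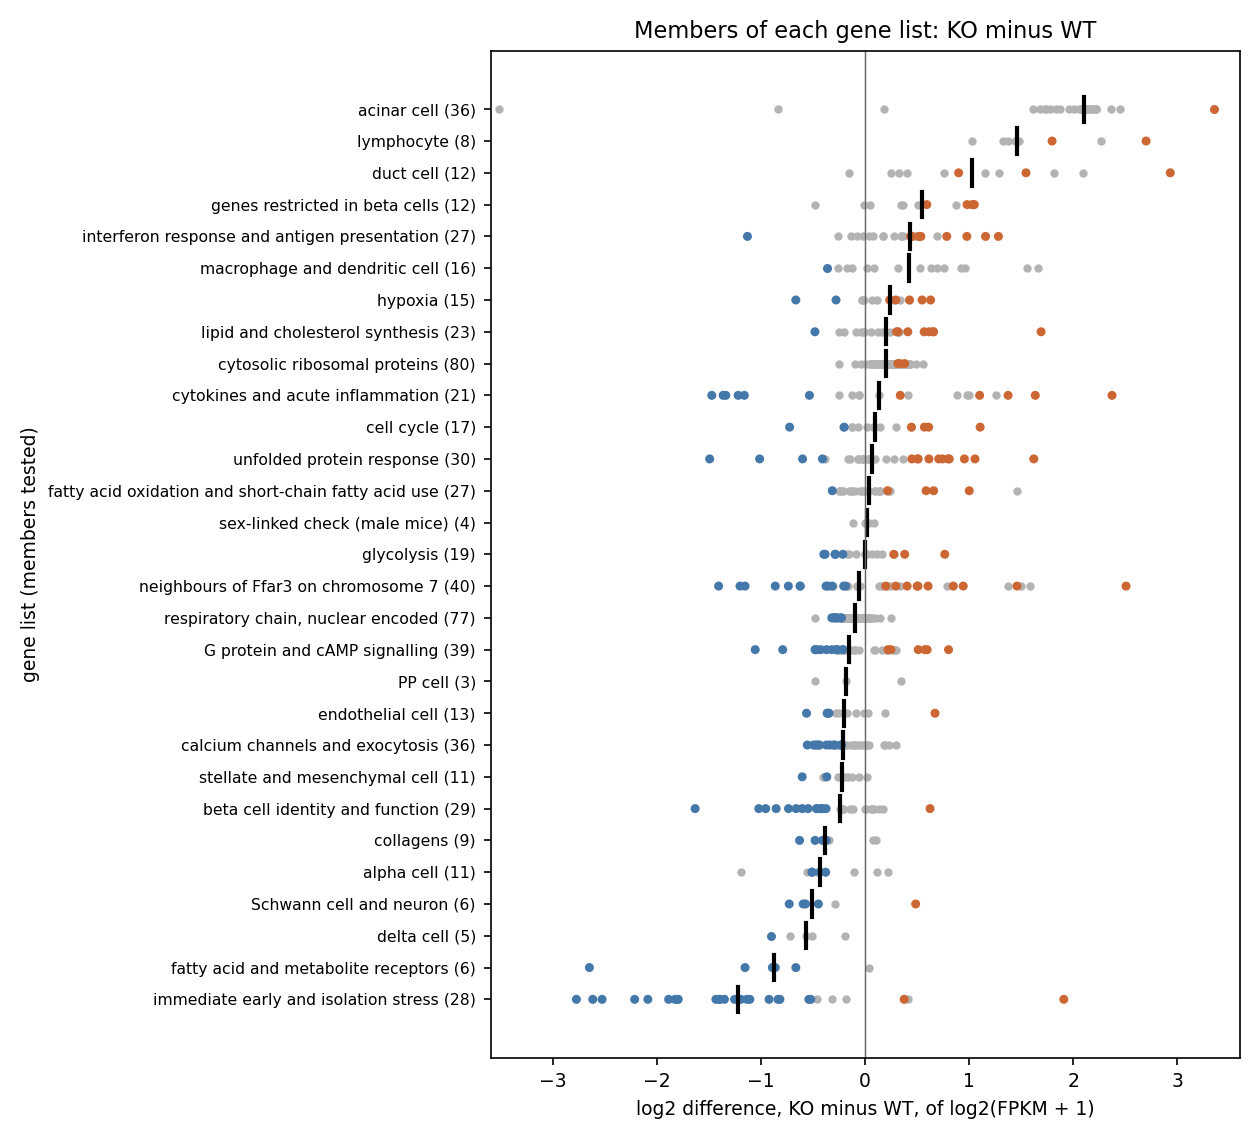
Each point is a tested gene of a list, placed by its log2 difference of KO minus WT (x axis); orange points rose, blue points fell and grey points did not pass, and black bars are list medians. The medians run from -1.22 for immediate early genes to 2.1 for acinar genes; 1 member, Ins1 in the beta cell list, lies outside the axis, which ends at 3.6.

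Ffar3 lies on chromosome 7 of mm10 at 30854330 to 30856178 on the minus strand, with its coding sequence at 30854937 to 30855893. The gene bodies of Ffar1 (30857390 to 30861564) and Ffar2 (30818348 to 30823775), both on the minus strand, lie 1.2 kb and 30.6 kb from that of Ffar3 at their nearest ends. Of 40 tested genes in the list of Ffar3 neighbours, 10 rose and 12 fell (12 and 14 adjusted over the list alone) and the set did not pass in either direction (adjusted p = 0.93). Prodh2 (30493622 to 30513402), which encodes a hydroxyproline dehydrogenase, rose from 0.0301 ± 0.0261 to 4.89 ± 0.812 FPKM (log2 difference 2.51, adjusted p = 0.00022). The proton pump gene Atp4a (30712209 to 30725534) fell from 3.79 ± 0.353 to 0.806 ± 0.127. Within 1 Mb of Ffar3, 15 of 53 genes were called with a difference of at least 0.5 log2, Ffar1 and Ffar2 among the 15. That count was higher than in 99.05% of runs of 53 consecutive tested genes elsewhere, where the highest was 21. The runs overlap, so the share is not a p-value.

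**Figure D5:**
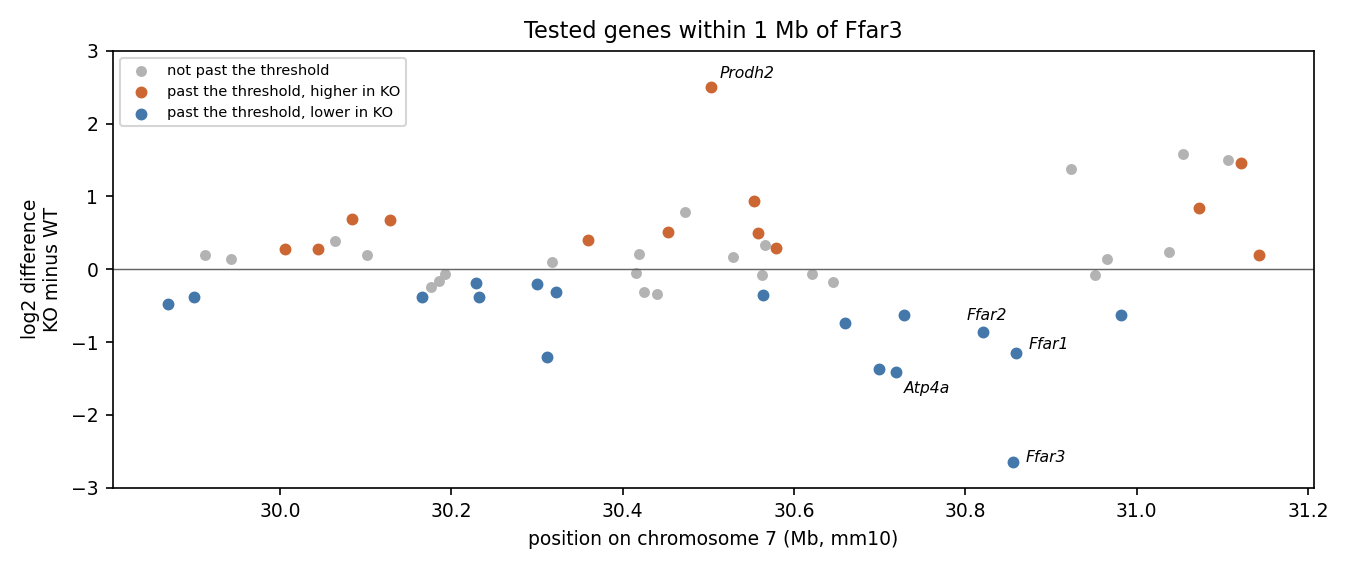
Log2 difference of KO minus WT (y axis) of Ffar3 and the 53 other tested genes within 1 Mb of it on chromosome 7, by the middle of the gene (x axis, Mb, mm10); colours show genes past the threshold, and names mark the genes given in the text. Among the named genes, Prodh2 was higher (2.51), and Ffar3, Atp4a and Ffar1 were lower (-2.65, -1.41 and -1.15).

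Libraries of the WT group were closely alike, with correlations of 0.990 to 0.994 across genes, against 0.956 to 0.980 within KO and 0.933 to 0.977 between the groups. For the gene sets, 15 of 29 passed with the preset correlation of camera, 7 higher and 8 lower. Splits of the 6 libraries that mixed the groups gave 7 to 14 passing lists with the same test. The count of passing lists therefore does not set the real groups apart. With an estimated correlation 0 passed, where the smallest adjusted p was 0.58. By fry, 3 passed: the fatty acid receptors, the immediate early genes and hypoxia.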

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

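The comparisons with KO replicate 1 alone (which take that library to vary like WT), the acinar covariate, the removed rows, the sums without insulin and the receptor list without Ffar3 were chosen after seeing the data. The covariate fit leans on KO replicate 1 as well, the only KO library with an acinar level near WT. Ffar3 kept its direction and call in each setting that tested it; its mean was too low for the filter at 5 FPKM. The 4657 calls became 3013 in KO replicate 1 alone and 2833 with the acinar covariate, of which 2640 and 2675 were among the 4657, and ranged from 2482 (without WT replicate 1; 2518 without WT replicate 3) to 5730 (without KO replicate 1) as libraries were left out. The 324 large differences became 542 with a pseudocount of 0.1, 194 at a mean of at least 5 FPKM (fewer genes tested), 532 with array weights, 210 in KO replicate 1 alone and 214 with the covariate, and 224 to 585 with libraries left out (585 without KO replicate 1). The 15 gene lists became 9 at a mean of at least 5 FPKM, 7 in KO replicate 1 alone, 7 with the covariate and 0 with an estimated correlation, and 11 to 13 with libraries left out. Without Ffar3 in the receptor list 15 lists passed. The acinar list reversed to -0.46 in KO replicate 1 alone and to -0.0074 with the covariate, which removes it by construction, and Mt1 reversed to -0.0531 under quantile normalization. The cause of the other changes was not tested. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.21, -0.09 and 0.03); with the replicate block 3865 genes passed. Calls were 50.8% higher in KO, 44.0% after quantile normalization and 60.6% with equal sums outside acinar and insulin rows. Of 152 named genes, 139 passed in the main fit. Of those 139, 31 lost their call without WT replicate 1 and 32 without WT replicate 3. Low values may be limited most in KO replicate 3, which by the estimate from low values had the fewest fragments per FPKM (59.5% of WT replicate 1). Total depth is unknown.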

Other observations

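The tests of explanations and splits, the serine, actin, B cell, clock, heat shock, metallothionein and aryl hydrocarbon receptor lists, and the genes named from them, Mafa, Iapp, Lyz2, Ddit3, Atf4, Ctrb1 and Cela2a were chosen after the results were seen. Of 15 tested genes of serine and amino acid synthesis and uptake, picked with their values in view, 14 were higher and 0 lower. Phgdh, the first enzyme of serine synthesis, was at 39.1, 74.6 and 112 FPKM in KO replicates 1, 2 and 3 against 19.7 ± 0.845 in WT (n = 3), Psat1 rose from 7.80 ± 0.542 to 26.6 ± 6.11, Asns from 76.7 ± 2.79 to 153 ± 37.8, and the transporter genes Slc1a4 from 6.81 ± 0.717 to 14.5 ± 0.502 and Slc7a5 from 77.0 ± 5.56 to 117 ± 5.07. In KO replicate 1 alone 11 of 13 rose. In KO the stress factor genes Ddit3 (390 ± 48.3 to 140 ± 33.4 FPKM) and Atf4 (406 ± 14.3 to 268 ± 26.9) fell. Actin, adhesion and stretch-response genes, a list made after Vcl and Myo1e were seen, had 15 of 24 higher and 1 lower, with Tpm1 from 24.1 ± 0.680 to 52.2 ± 8.13 and Zyx from 18.1 ± 2.40 to 30 ± 3.59 FPKM.

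The beta cell factor Mafa fell from 207 ± 8.52 to 101, 63.4 and 44.7 FPKM in KO replicates 1, 2 and 3. Iapp was at 35442 ± 1014 in WT and 30572 ± 2988 in KO (log2 difference -0.22, adjusted p = 0.80). In limma the spread of each gene is drawn toward that of genes with a like mean. At the highest means these include acinar genes that differ widely between KO libraries, so this p does not show that Iapp was unchanged. B cell and plasma cell genes had 6 of 14 higher and 0 lower in a list made the same way. Members near 0 in WT could pass the filter only through high KO values, so the direction of this count was partly fixed by it. Cd79a was at 15.8, 28 and 7.6 FPKM in KO replicates 1, 2 and 3 against 6.92 ± 0.437 in WT (adjusted p = 0.071, and 0.0054 without KO replicate 3). The macrophage gene Lyz2 was at 32.9, 94.8 and 10.3 against 10.3 ± 1.03 (adjusted p = 0.1, 0.0082 without KO replicate 3). Mt1 and Mt2, which bind metals, rose by log2 differences of 0.83 and 0.78. Their calls were lost without WT replicate 1 (adjusted p of 0.069 and 0.062) and WT replicate 3 (0.078 and 0.067), and under quantile normalization Mt1 was at -0.0531 and Mt2 at 0.33 (adjusted p = 0.61). Heat shock chaperones had 3 of 18 higher and 6 lower, clock genes 4 of 18 higher and 6 lower, metallothioneins 3 of 4 higher and 1 lower, and aryl hydrocarbon receptor targets 1 of 3 higher (Cyp1a1) and 1 lower.

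Of the 10 splits of the 6 libraries, 1, the real one, gave 4657 genes and 324 large differences, and the highest other split gave 0 of each. Each other split has KO and WT libraries on both sides, so the group difference adds to its residual spread. A count of 0 there is therefore no measure of how many of the 4657 calls are false. For gene lists the real split gave 15 and the other splits 7 to 14. With 10 splits no share under 0.05 can be had.

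The immediate early list had a lower FPKM sum in each KO library. Exocrine tissue in KO replicates 2 and 3 is argued against as the whole cause, since the median was -1.23 in KO replicate 1 alone. With the acinar level as a covariate 21 of 28 members were still lower and the median moved from -1.22 to -1.21. That fit leans on KO replicate 1, the only KO library with an acinar level near WT, so both medians rest on a single KO library. Another time of day could shift such genes: of 6 clock genes of the Dbp phase, 3 rose (Dbp, Tef, Nr1d2) and 1 fell (Hlf); Hlf lost its call without WT replicate 1, 2 or 3 (adjusted p of 0.067, 0.055 and 0.084) and Tef without WT replicate 3 (0.059), and genes that go both ways leave it open. Islet handling that differed between the groups could do so too. The list varied 2.63 times as much within groups as lists matched on mean expression, which decides nothing, because handling is not given in the sources used here. The median of the larger within-group range was 0.63 log2, smaller in size than the median difference of -1.22. Handling that was alike within each group would show in neither value, so handling cannot be told apart from genotype. The genotype stays among the open explanations, as untested.

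Genes around Ffar3 changed in both directions. Within 1 Mb, 15 of 53 genes were called at 0.5 log2 or more, 7 higher and 8 lower. That was more than in 99.05% of overlapping runs of 53 consecutive tested genes elsewhere (median 7, highest 21). This is consistent with DNA at or linked to the targeted allele, such as flanking sequence of another strain, as a candidate source of the differences in Prodh2 and Atp4a; no sequence was analysed here. For Ffar1, a lower share of beta cells is argued against, since the beta cell list without Ins1 had a median of -0.309 (SD 0.45) against -1.15 for Ffar1. Whether the altered locus or the loss of the receptor lowered Ffar1 and Ffar2 was not tested.

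High acinar transcripts in KO replicates 2 and 3 may be exocrine tissue carried over in 2 pools. Of 34 acinar markers, 94.1% were higher in KO replicate 3 than in KO replicate 1 by a fold within 0.5 log2 of the median of 21.8, as transcripts from 1 source would; Ctrb1 was at 4406 and 92308 FPKM in these libraries and Cela2a at 3877 and 81270. A change of acinar transcripts in every KO library is argued against, since KO replicate 1 was not above the highest WT library at 33 of the 34 markers. A change in acinar cells of 2 of the 3 pools stays open and was not tested.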
